A study of Mus musculus with 21 samples.

How the data were processed

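Ventricle RNA of mice at 8 weeks of age was measured on 7 Exiqon and 14 Agilent arrays. The RNA of the Exiqon arrays was extracted with Trizol and labelled with a Hy3/Hy5 power labelling kit, per the labels, with the sample in Hy3 and a common reference pool in Hy5. The extraction for the Agilent arrays is not given in the sources used here, and their dye was Cy3, per the labels. The Agilent scanner files hold spot intensity values from Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes, background-subtracted and spatially detrended for each array, with no scaling between arrays. The Exiqon files hold spot and local background intensity values in tables of format version 7.0.0, 1 per channel, per the file headers, with no background correction. Which table holds Hy3 was checked on control spots that carry Hy3 only. The authors also deposited processed values on a log2 scale. For Agilent every column of these holds the same sorted values (median 3.63), in the rank order of the scanner's total gene signal (rank correlation 1). For Exiqon they are log2 ratios of Hy3 over Hy5 that follow the scanner ratios (rank correlation 0.929 to 0.979), with medians of 0.01 to 0.075, and 239 to 256 of 514 are filled in per array. How the authors normalized and centred either set is not given in the sources used here. A deposited table of raw intensity values holds the Agilent total gene signals, equal for 100% of 12033 spots within a relative tolerance of 0.001.

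The column names of that table carry a code for each RNA. They show that the replicate numbers in the Agilent labels name different RNAs on the slides, except for R9C 1. Averaging by number, as planned before the data were examined, would make R9C 2 and R9C 3 each a mean of the same 2 RNAs, and WT 1 and WT 2 likewise. The main analysis therefore departs from the plan and averages the 2 arrays of each code, giving 3 R9C and 2 WT RNAs numbered as on slide 1, which was settled before any calls were compared. The result of the plan as written is printed beside it. The internal control, whose content is not given in the labels, entered no test between groups in the main analysis. An alternative fit held it as a group of its own, and some of its values are printed beside those of R9C and WT.

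For the Agilent arrays, control spots were left out, which left 11080 of 12033 spots for 534 miRNAs, and so were outlier spots. Processed signals of replicate spots were averaged and those of a miRNA's probes were summed. Each array was scaled to its percentile 75 over the 195 probes detected on all arrays, with factors from 0.283 to 2.02, then raised to a floor of 11.3, the median over arrays of the lowest scaled signal well above background, and put on a log2 scale. A miRNA was tested if a probe was well above background in a share of at least 0.5 of its spots on every array of a group, which left 132, and 0 spots were saturated. For the Exiqon arrays, which have 9792 spots and 4 spots per probe, the background was corrected with normexp (offset 50), ratios were normalized with loess within each array, and spots and then probes were averaged. A probe was kept if Hy3 exceeded the local background mean by 2 background SDs in a share of at least 0.5 of its spots on every array of a group, which left 480, of which 73 are sequences the array maker calls miRPlus. This filter is lenient, since a share of 0.893 to 1 of the negative control spots passed it. Where a miRNA had several probes, they differed in sign for 2 of 76 on Agilent and 2 of 3 on Exiqon, and for 0 with both over 0.1 in size. miRNA names are those of the array designs and can be old.

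R9C was compared with WT on each platform with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. In all, 16 lists of miRNAs were fixed before the data were examined, together with the groups, the tests, the alternatives and the rule for naming miRNAs: muscle miRNAs, let-7, miR-30, miR-29 and miR-15/16 families, miR-17-92 and related clusters, miR-23/24/27 clusters, miRNAs raised in the stressed heart, miRNAs reported to limit and to promote cardiomyocyte death, fibroblast and smooth muscle, endothelial, blood and immune cells, the imprinted Dlk1-Dio3 cluster, other tissues, and steady reference miRNAs. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, then an estimated correlation) and fry of limma, adjusted over the lists. The rule named, per platform and direction, up to 10 called miRNAs with the smallest p, or the 5 smallest where fewer than 5 passed, all tested muscle miRNAs, up to 4 called members per list, and miRNAs that passed on both platforms. Other called members and some uncalled members of lists, and the miRNAs of opposite sign on the platforms, were named after their values were seen. The platforms were compared over miRNAs matched by name, with an exact permutation of the Exiqon groups.

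The limma tests were tried on simulated, already normalized values with the spread of the real arrays, in 20 draws with 10 changed miRNAs per size. Background correction, scaling, floor, filter and probe summary were not part of the simulation. For the comparison of R9C with WT on the Agilent arrays (132 miRNAs), 6.5%, 44.5% and 87% of changes of 0.5, 1 and 2 log2 units were recovered, and 4.83% of calls were false. On the Exiqon arrays (480) these were 89.5%, 97.5% and 100%, and 5.44%. A list moved by −0.5 log2 units was called in 45% of the Agilent draws and 100% of the Exiqon draws, and 0.385% and 0.714% of the unchanged lists were called. The draws made miRNAs independent of each other, whereas members of the real lists had estimated correlations of up to 0.898 on Agilent and 0.57 on Exiqon. These list rates therefore do not carry over to the real lists. The rates for single miRNAs likewise hold for independent miRNAs and may differ on the real arrays. Alternatives covered the background correction, scaling, filter, probe summary, slides, internal control, variance model, deposited values, replicate block, threshold and each replicate left out.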

Results

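miRNAs were measured in ventricle tissue of mice at 8 weeks of age. One group carried a transgene for a mutant of phospholamban, the small membrane protein that restrains the calcium pump of the sarcoplasmic reticulum, and is called R9C after its sample titles. The other group (WT) held healthy littermates. The transgene leads to dilated cardiomyopathy, in which the ventricles enlarge and contract weakly, and the comparison asks which miRNAs differ at an early stage of the disease. The contrast was measured on 2 platforms with 21 arrays in all. On the Exiqon arrays, 4 R9C and 3 WT samples were each labelled with Hy3 and hybridised against a common reference pool labelled with Hy5. The Agilent arrays have 1 colour and probes named for human and viral miRNAs, and 14 of them lay on 2 slides: 3 R9C RNAs, 2 WT RNAs and 2 internal control RNAs, each on both slides. The labels do not say which samples came from separate animals, or whether both platforms received the same animals, so p-values measure the spread between these samples, which may be technical. On the Exiqon arrays the median Hy3 signal of mouse miRNA spots lay between 59.2 and 81.9 units above local background, and that of the negative control spots between 16.7 and 28.0 units. On the Agilent arrays 18.6% to 31.9% of the spots were well above background. The number of arrays limits the precision of every difference.

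On the Exiqon arrays, miR-21, which is abundant in cardiac fibroblasts, was 3.82-fold higher in R9C than in WT ventricle, with a log2 ratio to the pool of 0.65 ± 0.31 (SD, n = 4) against −1.28 ± 0.17 (SD, n = 3). miR-214 and miR-199a-5p, which are processed from one long transcript, were 2.18-fold and 2.01-fold higher. The miR-34 family, which p53 induces, rose in its 3 tested members: miR-34b-5p by 0.91 log2 units, miR-34a by 0.79 and miR-34c by 0.64. miR-146b, miR-146a and miR-223, which are induced in inflammation or carried by myeloid cells, rose by 0.79, 0.63 and 0.77 log2 units. miR-499, encoded within a cardiac myosin heavy chain gene, fell by 0.76 log2 units, from 0.48 ± 0.12 (SD, n = 3) in WT to −0.28 ± 0.24 (SD, n = 4) in R9C.

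By limma, 44 of 480 miRNAs and array-maker sequences were higher and 20 were lower in R9C at an adjusted p under 0.05, and 72 and 60 at an unadjusted p under 0.05. The R9C and WT values did not overlap for 63 of the 64 calls, and for 25.4% of everything tested, where chance gives 5.71%. The calls had a median size of 0.40 log2 units and the smallest was 0.19. limma gave an adjusted p of 4.2e-04 for miR-21 (SE 0.17), 0.00509 for miR-214 (SE 0.18), 0.00437 for miR-199a-5p (SE 0.15) and 0.00589 for miR-499 (SE 0.13). The smallest adjusted p values by limma belonged to miRPlus_17900 (2.28e-05, log2 difference 1.52) and miRPlus_17841 (6.34e-05, log2 difference 0.98), which are sequences of the array maker and among 4 of its 73 tested sequences that passed. miR-146b and miR-223 each had 8.48e-05, and miR-146a had 5.89e-04. Other miRNAs with small p values were miR-24, which rose by 0.33, and miR-19a, which also rose by 0.33 log2 units. miR-30e*, the second arm of a miR-30 precursor, fell by 0.52, miRPlus_17653 fell by 0.49, miR-378*, encoded within the gene of a mitochondrial coactivator, fell by 0.41, and miR-9*, of a brain-enriched precursor, fell by 0.19. miR-150, which lymphocytes carry, fell by 0.31, miR-155, induced in activated immune cells, fell by 0.29, and miR-25 fell by 0.29. In the authors' deposited log2 ratios, which allowed 229 miRNAs to be tested, the calls split into 31 higher and 31 lower. The scanner values of the 224 probes with a deposited value on every array gave 31 higher and 27 lower, and those of the 337 above the negative control spots gave 45 and 27. With median centring in place of loess, 35 were higher and 10 lower. Without R9C replicate 4, 47 were higher and 31 lower, and miR-133a lost its call in 9 of 21 alternatives and miR-486 in 5.

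**Figure D1:**
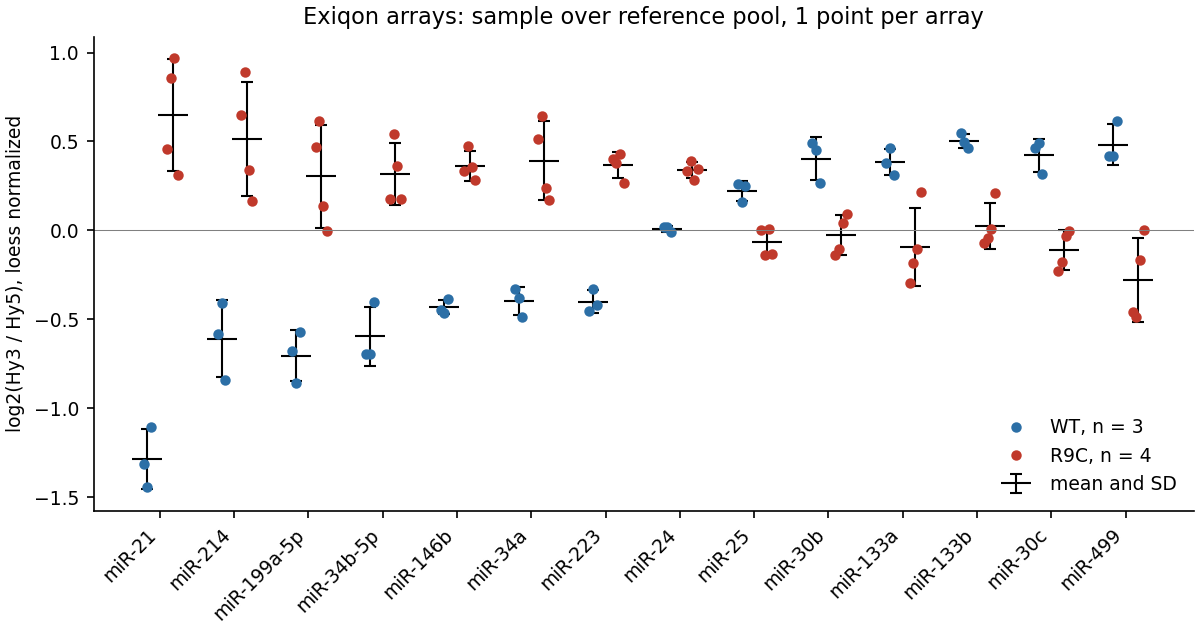
Normalized log2 ratio of sample to reference pool for 14 miRNAs on the Exiqon arrays, 1 point per array, with the mean and SD of 4 R9C and 3 WT arrays. All R9C points lie above all WT points for miR-21, miR-214, miR-199a-5p, miR-34b-5p, miR-146b, miR-34a, miR-223 and miR-24, and below them for the other 6.

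Grouped by lists fixed in advance, the miRNAs reported to rise in the stressed heart were higher as a list on the Exiqon arrays: 10 of 14 passed as higher, 11 when adjusted over the list alone, and none as lower, with a list median of 0.48 log2 units (adjusted p = 1.71e-08 by camera of limma at its preset correlation, 0.327 with an estimated correlation between members). miR-125b, miR-195, miR-132 and miR-212 did not pass by limma. Beside miR-21, miR-214 and the miR-34 family, they include miR-23a and miR-23b, which each rose by 0.30. All 5 members of the miR-23/24/27 clusters, whose miRNAs share primary transcripts, rose (5 when adjusted over the list alone), with a median of 0.33 (adjusted p = 1.4e-04 by camera of limma, 0.327 with the estimated correlation), for example miR-27a by 0.40 and miR-27b by 0.36. The miR-30 family, which is abundant in cardiomyocytes, was lower: miR-30c fell by 0.53, miR-30b by 0.43 and miR-30a by 0.33, while miR-30d (−0.28) and miR-30e (−0.37) passed only when adjusted over the list alone, which made 5 of 5. The family's median was −0.37 (adjusted p = 2.1e-04 by camera of limma, 0.327 with the estimated correlation). Of 7 muscle miRNAs, 4 were lower (4 when adjusted over the list alone), with a list median of −0.48 (adjusted p = 0.00681 by camera of limma, 0.327 with the estimated correlation). Beside miR-499 these were miR-133a and miR-133b, which restrain hypertrophy and each fell by 0.48, and miR-486, also abundant in red blood cells, which fell by 0.57. miR-451, a red blood cell miRNA, differed by −0.52 (adjusted p = 0.056 by limma, 0.0119 adjusted over its list alone), and miR-144, its neighbour on one transcript, by −0.01. The differences of miR-1 (−0.16), miR-206 (0.02) and miR-208 (0.14) did not pass, with adjusted p of 0.495, 0.964 and 0.895 by limma. With the estimated correlation none of the 16 lists passed by camera (1 at an unadjusted p under 0.05), while fry of limma, which asks whether members move one way on balance, called 10 of 16. The muscle list lost its call when the Exiqon ratios were also quantile normalized (median −0.11, adjusted p = 0.139) or Hy3 was used alone (median −0.13, adjusted p = 0.221 by camera). With Hy3 alone miR-133a differed by −0.18 (SE 0.10) and miR-133b by −0.13 (SE 0.06), against −0.48 (SE 0.11) and −0.48 (SE 0.07) as ratios, and did not pass (adjusted p = 0.305 and 0.202 by limma), while miR-499 (−0.64) and miR-486 (−0.50) passed. Of the 35 splits of the 7 samples, 9 called as many lists as the 4 found here.

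Markers of other cells of the heart moved unevenly on the Exiqon arrays. In the fibroblast and smooth muscle list 3 of 9 passed as higher (3 when adjusted over the list alone), namely miR-21, miR-199a-5p and miR-214, which the stressed heart list also holds, while the smooth muscle miRNAs miR-143 (−0.06) and miR-145 (−0.13) did not pass. The list's median was 0.25 (adjusted p = 0.135 by camera, 0.327 with the estimated correlation and 0.00402 by fry of limma), and it passed in 3 of 6 other ways of processing the arrays, for example with median centring in place of loess (adjusted p = 0.00831 at the preset correlation). In the endothelial list 2 of 6 were higher (2 when adjusted over the list alone), miR-222 by 0.60 and miR-221 by 0.40, with a list median of 0.07 (adjusted p = 0.213 by camera and 0.0139 by fry), and both arms of miR-126, the main endothelial miRNA, did not pass (−0.03 and −0.13). In the blood and immune list 2 of 9 were higher and 3 lower (2 and 4 when adjusted over the list alone), with a median of −0.01 that changed sign between normalizations (adjusted p = 0.819 by camera and 0.164 by fry).

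For miRNAs reported to limit or to promote cardiomyocyte death on the Exiqon arrays, camera called neither list against the other miRNAs, while fry of limma called both as higher on balance (adjusted p = 0.00542 and 0.0345). Of the 17 reported to limit it, 7 were higher and 5 lower (7 and 7 when adjusted over the list alone), with a median of 0.13 (adjusted p = 0.673 by camera of limma). The higher members were miR-21, miR-24, miR-199a-5p, miR-214, miR-19a, miR-221 and miR-222. The lower members were miR-133a, miR-499, miR-30a, miR-30b and miR-30c. Of the 15 reported to promote it, 3 were higher and 0 lower (3 and 0 when adjusted over the list alone), all of the miR-34 family, with a median of 0.05 (adjusted p = 0.213 by camera of limma).

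**Figure D2:**
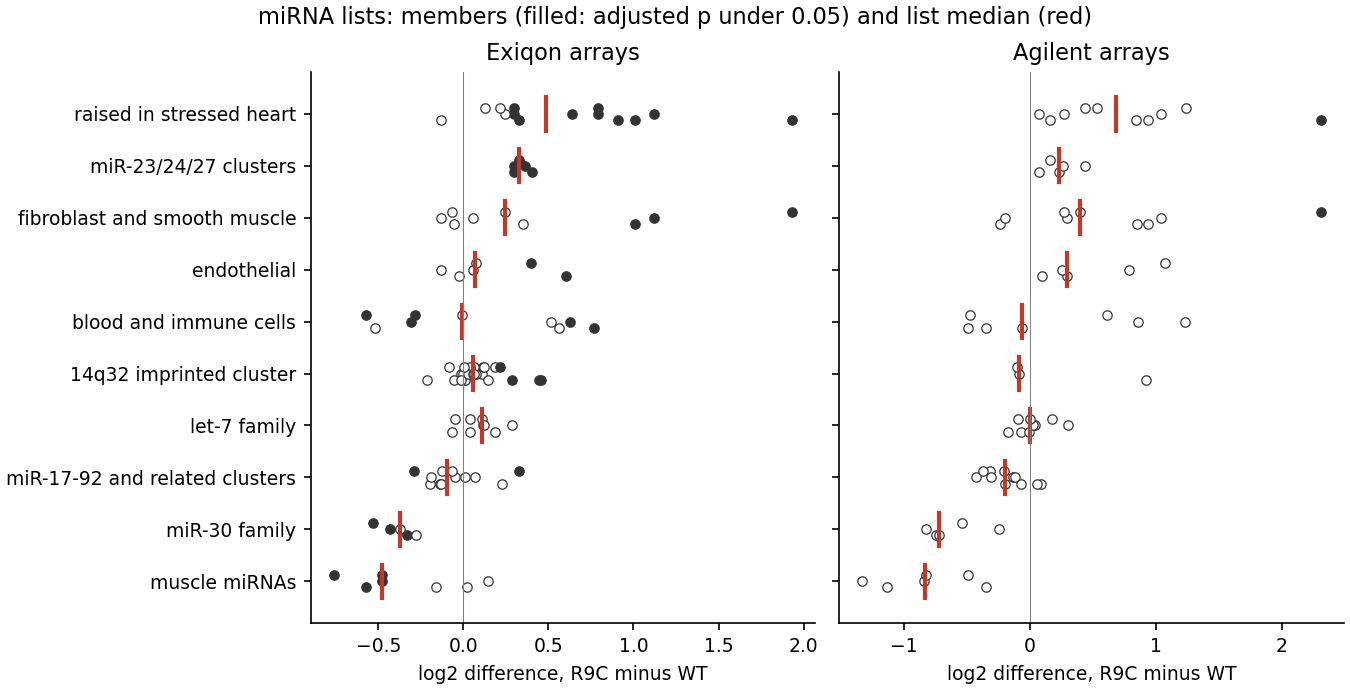
Log2 difference of R9C minus WT for the members of 10 lists on the Exiqon arrays and on the Agilent arrays, filled where limma's adjusted p was under 0.05, with the list median in red. The muscle list and the miR-30 family have medians of −0.48 and −0.37 on the Exiqon arrays and −0.83 and −0.72 on the Agilent arrays.

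On the Agilent arrays, miR-21 was 4.97-fold higher in R9C, with a log2 scaled signal of 10.76 ± 0.18 (SD, n = 3 RNAs) against 8.45 ± 0.48 (SD, n = 2 RNAs). The probe set named for hcmv-miR-US25-1, a miRNA of human cytomegalovirus, was also brighter in R9C, at 6.10 ± 0.54 (SD, n = 3 RNAs) against 3.52 ± 0.03 in WT, where the floor of the scale is 3.50. It was well above background on 6 of 6 R9C arrays, on 1 of 4 WT arrays and on 0 of 4 internal control arrays, and the signal came from 1 of its 4 probes. The next differences did not pass: miR-34a 1.24, miR-223 1.24 and miR-222 1.08 log2 units upward, and miR-499 −1.33, miR-133b −0.83, miR-133a −0.84, miR-30d −0.72 and miR-328 −0.81 downward. The other muscle miRNAs, which did not pass either, were miR-208, encoded within a second cardiac myosin gene, at −1.14, miR-486 at −0.49 and miR-1 at −0.35. The difference of hsa-miR-208 on the Agilent arrays was −0.34 without R9C replicate 2, that of hsa-miR-328 on the Agilent arrays −0.34 without WT replicate 2, and those of miR-133a and miR-133b were 0 with quantile normalization and in the deposited values. Over the alternatives the difference of miR-34a was 0.60 to 1.42, that of miR-223 0.48 to 1.56 and that of miR-222 0.19 to 1.26. miR-451 differed by −0.48 (adjusted p = 0.357 by limma).

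By limma, 2 of 132 miRNAs were higher and 0 were lower at an adjusted p under 0.05, and 16 and 5 at an unadjusted p under 0.05. Both calls had an adjusted p of 0.00967 by limma (SE 0.28 for miR-21). For hcmv-miR-US25-1 the floor set the spread of WT, so its p does not rest on a measured spread in that group. The smallest adjusted p by limma among the downward differences was 0.211. The values of the groups did not overlap for 40.2% of the miRNAs, where chance gives 20%. Within slide 1 and slide 2 alone, limma called 2 and 1 miRNAs higher and 0 lower (2 and 5 lower at an unadjusted p under 0.05), and miR-21 differed by 2.30 and 2.33. With all 10 arrays as samples and the slide as a block, 17 were higher and 11 lower, and with the RNA as a random block as well, 5 were higher and 0 lower (limma, 12 lower at an unadjusted p under 0.05). Averaged by the number in the labels, which joins different RNAs on the slides, 14 were higher and 8 lower. hsa-miR-21 on the Agilent arrays differed by 1.90 to 2.65 in all 24 alternatives and lost its call in 3: without WT replicate 2 (adjusted p = 0.294 by limma), where 1 WT RNA is left and R9C alone gives the spread, when all probe sets were tested (0.126) and in the deposited values (0.0638). hcmv-miR-US25-1 lost its call in 8 of 23 alternatives, among them without either WT replicate, and in a further one, normexp background correction, its difference was −0.077.

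**Figure D3:**
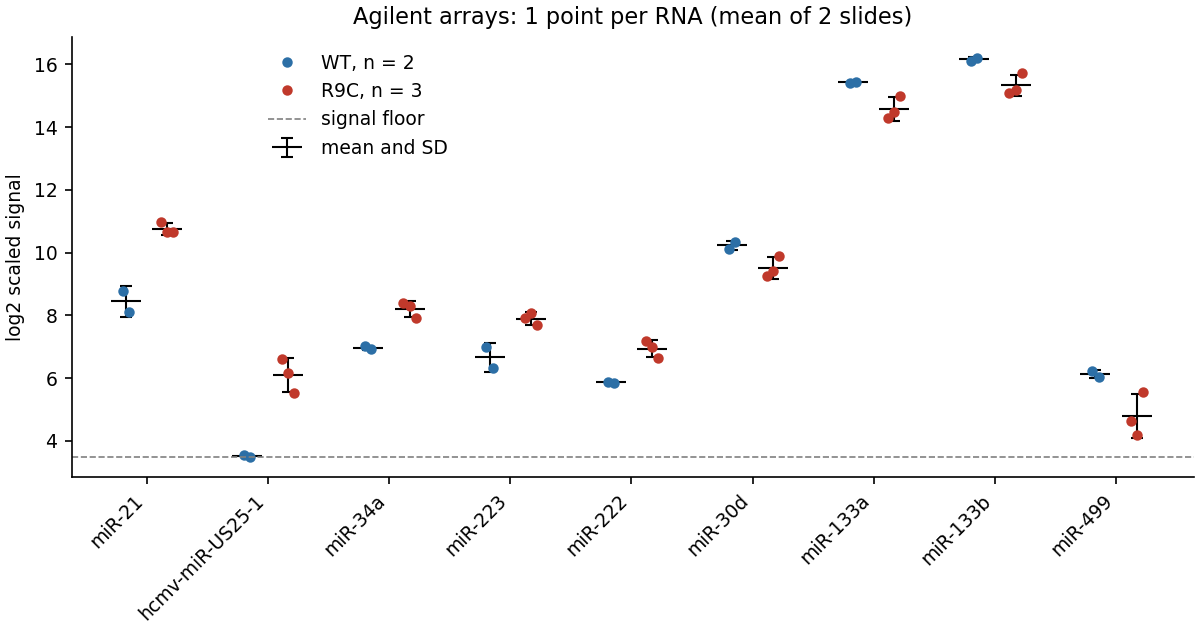
Log2 scaled signal on the Agilent arrays, 1 point per RNA as the mean of its 2 slides, with the mean and SD of 3 R9C and 2 WT RNAs and the signal floor as a dashed line. miR-21 lies at 10.76 in R9C and 8.45 in WT, and hcmv-miR-US25-1 in WT lies at the floor.

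Grouped by list, the Agilent arrays gave 1 of 10 miRNAs raised in the stressed heart as higher, 3 when adjusted over the list alone, with a median of 0.68 (adjusted p = 6.59e-05 by camera of limma at its preset correlation). With an estimated correlation this list and the 4 that follow each had an adjusted p of 0.573. The muscle list had 0 of 6 called by limma, 3 lower when adjusted over the list alone and a median of −0.83 (adjusted p = 0.0102 by camera), and the miR-30 family had 0 of 5 and 0 when adjusted over the list alone, with a median of −0.72 (adjusted p = 0.0374 by camera). In the fibroblast and smooth muscle list 1 of 9 was higher (3 when adjusted over the list alone), with a median of 0.40 (adjusted p = 0.0133 by camera), and in the endothelial list 0 of 5 (2 higher when adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0374 by camera). Relative to the median of all miRNAs, which was −0.0785 here, these list medians were 0.763, −0.756, −0.641, 0.48 and 0.373. With the estimated correlation none of the 15 lists tested passed by camera, and fry of limma called 0 (4 at an unadjusted p under 0.05). Within slide 1 and slide 2 the stressed heart list had medians of 0.66 and 0.71, the muscle list −0.81 and −0.86, the miR-30 family −0.66 and −0.78, the fibroblast and smooth muscle list 0.31 and 0.49, and the endothelial list 0.27 and 0.34. Both slides carried the same RNAs, so their results repeat one comparison. At the preset correlation all 5 passed within each slide by camera of limma except the miR-30 family on slide 2 (adjusted p = 0.0817). All passed with the slide as a block (adjusted p from 3.45e-05 to 0.0465 by camera), but that fit counts both arrays of each RNA as separate samples. Quantile normalization ended the calls of the muscle list (median −0.38, adjusted p = 0.198), the miR-30 family (−0.72, 0.0634), the fibroblast and smooth muscle list (0.37, 0.0517) and the endothelial list (0.30, 0.0517), all by camera. The percentile over all probes ended those of the miR-30 family (0.0862) and the endothelial list (0.128), and normexp that of the endothelial list (0.108). Relative to the median of all miRNAs, the medians were −0.641 and 0.373 with that percentile, and 0.346 for the endothelial list with normexp. With normexp the fibroblast and smooth muscle list had a median of 0.0946 (0.314 relative to all miRNAs) and kept its call (adjusted p = 5.4e-04 by camera). The miR-30 family also lost its call without R9C replicate 1 (adjusted p = 0.177) or WT replicate 1 (0.12), the fibroblast and smooth muscle list without R9C replicate 2 (0.158), and the endothelial list without R9C replicate 2 (0.348) or WT replicate 2 (0.106).

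The lists of miRNAs tied to cardiomyocyte death passed neither by camera nor by fry of limma on the Agilent arrays. Of 17 reported to limit it, 1 was higher, miR-21, and 0 lower (4 and 1 when adjusted over the list alone), with a median of −0.10 (adjusted p = 0.82 by camera of limma), which was −0.0233 to 0.0333 relative to all miRNAs over the normalizations. Of 10 reported to promote it, 0 were called by limma (1 higher when adjusted over the list alone, miR-34a), with a median of 0.11 (adjusted p = 0.406 by camera; 0.17 to 0.19 relative to all miRNAs). The miR-23/24/27 clusters had 0 of 5 called and 0 when adjusted over the list alone, with a median of 0.23 (adjusted p = 0.332 by camera), and passed with normexp background correction (0.0119). The blood and immune list had 0 of 7 called (1 higher when adjusted over the list alone, miR-223), with a median of −0.06 (adjusted p = 0.63 by camera; 0.00553 to 0.095 relative to all miRNAs).

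Among the miRNAs tested on both platforms, miR-21 had the highest difference on each and was the 1 miRNA that passed on both. Of the 22 miRNAs that rose on the Exiqon arrays and were tested on both platforms, 20 had a positive difference on the Agilent arrays, among them miR-214 (1.04), miR-199a (0.94), miR-34a and miR-223. Of the 12 that fell, 11 had a negative difference there, among them miR-499, miR-133a and miR-133b. The other 3 had opposite signs: miR-19a had 0.33 on the Exiqon and −0.21 on the Agilent arrays, miR-574-3p 0.27 and −0.04, and miR-324-3p −0.24 and 0.08. At an unadjusted p under 0.05 by limma, 17 miRNAs passed on both platforms in the same direction and 0 in opposite directions. Across the 111 miRNAs tested on both, which are not independent replicates, the differences had a Spearman correlation of 0.684 and a Pearson correlation of 0.789, and 75.7% had the same sign. A two-sided exact permutation of the 7 Exiqon samples gave p = 0.143 for either correlation and 0.0857 for the shared sign, where the smallest p the 35 splits allow is 0.0286. In its own direction, 2 of the 35 splits, the real one included, reached as high a Spearman correlation, and the highest of another split was 0.714.

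**Figure D4:**
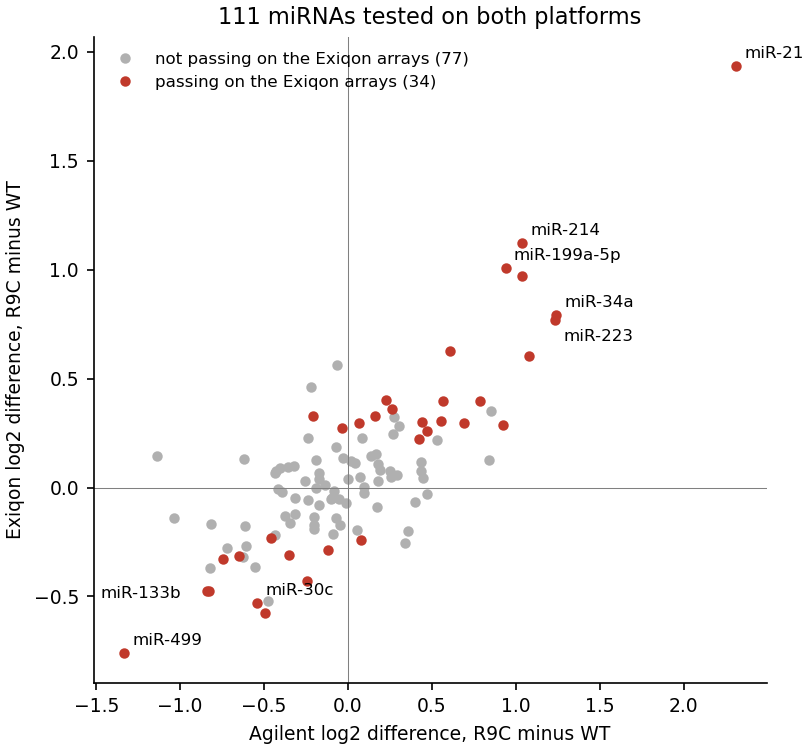
Log2 difference of R9C minus WT on the Agilent arrays (x axis) and the Exiqon arrays (y axis) for the 111 miRNAs tested on both, in red the 34 that passed on the Exiqon arrays. Of these 34, 31 have the same sign on both axes.

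Over the 111 miRNAs detected on all 14 arrays, the median SD between the slides for one RNA was 0.0925 log2 units, from 0.0642 to 0.15 between RNAs, against 0.273 between the R9C RNAs, 0.131 between the WT RNAs and 0.164 between the internal control RNAs. These SDs are not on one footing. The SD between slides came from single arrays, and those between RNAs from means of 2 arrays, with 3 R9C RNAs but 2 in each other group. An SD of 2 values tends to be lower, so the R9C and WT figures cannot be compared directly. With the percentile over all probes the median SD between the slides was 0.15. The Pearson correlation between slides across miRNAs lay between 0.977 and 0.998.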

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

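The test of the hcmv-miR-US25-1 signal was chosen after the result was seen.

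Among 39 miRNAs named in the text, 2 had an Exiqon R9C sample far from the other 3, where chance gives about 1 in 20. For miR-206, R9C replicate 1 had a log2 ratio of −0.01 against 0.38 to 0.42 in the others, a gap of 0.92 of the group's range. For miR-208, R9C replicate 1 had −0.605 against 0.70 to 0.93, a gap of 0.848 of the range.

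Of 1596 Exiqon probes not designed for mouse, 559 lay above the negative control spots, and 75 of these passed by limma in R9C against WT (13.4%, against 13.3% of the tested miRNAs and array-maker sequences), 35 higher and 40 lower, with log2 differences from −0.912 to 1.08. The 2 shares rest on unlike filters, since the miRNAs passed the more lenient local background filter. Of the 337 miRNAs and array-maker sequences above the negative control spots, 45 were higher and 27 lower.

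On the Agilent arrays, the probe set named for hcmv-miR-US25-1, a viral miRNA outside the study's question, had a mean log2 signal of 6.10 in R9C, above the internal control arrays at the floor. All 3 R9C arrays of each slide were well above background, against 1 and 0 of 2 WT arrays. The filter tested a miRNA only if every array of R9C or of WT was well above background. The R9C result was therefore fixed in advance, and a defect of one slide cannot be judged from it. The signal came from 1 of 4 probes, and another RNA bound by that probe was not tested and stays open. Its difference was −0.077 with normexp background correction (adjusted p = 0.894 by limma, 3.79e-06 to 0.894 over the alternatives). That setting also added an offset of 50 to every spot before scaling and summing. The offset and the way background was removed cannot be told apart here, so both stay open. No biological explanation was tested.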

How the results depend on the processing

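The Agilent averaging by RNA code, the RNA code as a random block, the raw signals table, the left-out slide 1 array, the Exiqon negative control and deposited-probe filters, the slide spread alternatives and the lists without each replicate were chosen after the data were seen. Under alternatives, named miRNAs kept their direction and side of the threshold in 251 Agilent and 757 Exiqon values, lost the call in 11 and 38, gained it in 41 on Agilent, and changed sign in 2 and 14. The other 4 Agilent values were 0: miR-133a and miR-133b with quantile normalization and in the series matrix, where each had the same rank, and so the same value, on every array. Signal over background limits both platforms: most Agilent probes are dim, and Exiqon negative controls pass the local filter.

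Agilent higher calls, 2 in the main analysis, were 1 with quantile normalization, normexp, slide 2 alone or the raw signals table, 0 with no filter (11 higher and 4 lower at an unadjusted p under 0.05 by limma; 534 miRNAs tested) or series matrix values (15 and 10), 4 with detection in both groups, 5 with the internal control as a group of its own, the RNA code as a random block or an adjusted p under 0.1. They were 17, and lower calls 11, with 10 arrays and the slide as a block, and likewise with the source name as a random block, where each RNA counts as several samples. Averaged by label number they were 14 and 8. Without each replicate they were 0 to 3 higher and 0 to 1 lower, with 0 higher without WT 2 (5 unadjusted) and 1 lower without R9C 3. Agilent lists numbered 1 with quantile normalization and 3 to 5 without each replicate. The slide spread was 0.15 with the percentile over all probes. The median of all Agilent differences, −0.0785, was 0.104 with that percentile and −0.219 with normexp.

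Exiqon lower calls, 20 in the main analysis, were 10 with median centring, 31 in the series matrix values and 38 at an adjusted p under 0.1. Without each replicate they were 17 to 31, and higher calls 36 to 47. The planned raw signals alternative was not run for Exiqon, since that table holds Agilent arrays. miR-133a lost its call in 9 of 21 alternatives. The Spearman correlation of the platforms was 0.588 to 0.786, with p from 0.1 to 0.333.

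These values changed sign, and the cause was not tested. hcmv-miR-US25-1 was −0.077 with normexp. miR-1 on Agilent was −0.65 to 0.023 without each replicate, above 0 without R9C 1. On Exiqon miR-1 was 0.090 with loess and quantile and 0.059 with Hy3 alone. miR-206 was −0.0094 with background subtraction, −0.024 with median centring, −0.083 in the series matrix and −0.059 to 0.14 without each replicate. miR-208 was −0.083 to 0.50 without each replicate.

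The replicate numbers showed no steady pairing of the samples, though the check cannot settle it. Same-numbered deviations correlated at 0.031, −0.31 and 0.47 on Exiqon, the last being the highest of any R9C and WT pair there. On Agilent they correlated at −0.57 and −0.56, where centring makes the 2 WT RNAs mirror each other. With the number as a replicate block, Agilent gave 2 higher and 2 lower, Exiqon 45 and 26, with miR-206 −0.018 and miR-208 −0.012.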

Other observations

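The tests of cell composition, of the label number and of the normalization for single miRNAs were chosen after the result was seen.

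In the imprinted Dlk1-Dio3 cluster, a large group of miRNA genes expressed from the maternal allele, 4 of 26 miRNAs were higher in R9C on the Exiqon arrays and 0 lower (4 and 0 when adjusted over the list alone). miR-379 rose by 0.46, miR-411 by 0.45, miR-127 by 0.29 and miR-377 by 0.22 log2 units, though miR-127 lost its call in 8 of 19 alternatives and miR-377 in 2 of 19, and the list median was 0.06 (adjusted p = 0.0518 by camera of limma, 0.327 with an estimated correlation, 0.00722 by fry; by camera 0.0449 without R9C replicate 1 and 0.0494 with the brightest probe). On the Agilent arrays 0 of 3 were called by limma or when adjusted over the list alone, miR-127 differed by 0.92, and the median was −0.09 (adjusted p = 0.63 by camera; −0.00944 to 0.123 relative to all miRNAs over the normalizations). Of the miR-17-92 and related clusters, whose miRNAs are tied to cell growth, miR-19a rose and miR-25 fell, 1 and 1 of 12 (1 and 1 when adjusted over the list alone), with a median of −0.10 (adjusted p = 0.213 by camera, 0.645 with an estimated correlation, 0.515 by fry; by camera 0.0119 without WT replicate 2). On the Agilent arrays 0 of 11 were called, also when adjusted over the list alone (median −0.20, adjusted p = 0.368 by camera).

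The let-7 family, abundant in differentiated tissue, had 0 of 9 called by limma on the Exiqon arrays (median 0.11, adjusted p = 0.30 by camera and 0.0388 by fry) and 0 of 9 on the Agilent arrays (median 0.0022, 0.0374 to 0.206 relative to all miRNAs, 0.82). The miR-29 family, which represses collagen genes, had 0 of 3 on both (medians 0.13 and −0.22, adjusted p = 0.625 and 0.406 by camera). The miR-15/16 family had 0 of 6 on both (medians 0.01 and 0.31, relative to all miRNAs 0.00365 to 0.057 and 0.192 to 0.385, 0.691 and 0.368). miRNAs of other tissues had 0 of 18 on the Exiqon arrays (median −0.02, 0.286), and steady reference miRNAs 0 of 6 on both (medians −0.13 and −0.11, the second −0.0337 to −0.00467 relative to all miRNAs, 0.26 and 0.63). Adjusted over the list alone, these counts were 0 except 1 lower steady reference miRNA on the Exiqon arrays. Across miRNAs the internal control RNAs correlated with the WT mean at 0.993 and with the R9C mean at 0.973, and their miR-208 was 7.98 and 9.07 against 6.56 in WT.

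On the Exiqon arrays miR-21, miR-199a-5p and miR-214 were higher and muscle miRNAs lower in R9C. A lower share of cardiomyocyte RNA, with the other cells in unchanged proportions, would raise markers of those cells alike. The other 11 tested fibroblast, smooth muscle and endothelial miRNAs differed by 0.12 log2 units on average (95% interval 0.0376 to 0.202, highest 0.60), against 1.01 for the lowest of the 3. The 3 were picked because they passed in these same data, so their place above the other 11 was largely set by that choice. The values show only that the other 11 rose little on average (lowest −0.133). They cannot decide on such an even shift. A larger share of 1 other cell type, such as fibroblasts, was not tested and stays open. On the Agilent arrays the other 10 had a mean of 0.358 (−0.0774 to 0.794). There miR-222 (1.08) exceeded miR-214 (1.04) and miR-199a (0.94) in the main analysis, so only miR-21 stood apart. Over the alternatives miR-222 was 0.19 to 1.26, so this order may depend on the processing. For the muscle miRNAs a lower share of cardiomyocyte RNA was not tested. The reference channel alone gave 0 of the 64 calls in the opposite direction by limma (2 at an unadjusted p under 0.05), and with the sample channel alone 93.8% of the calls had an unadjusted p under 0.05 in the same direction and 47 passed, with miR-214 at 1.04 as the lowest of the 3 and miR-486 at −0.50 and miR-499 at −0.64, which argues against the reference and, for these 5, the normalization within arrays. For miR-133a (−0.18) and miR-133b (−0.13 with the sample channel alone, passing with median centring at −0.47), which rank 3 and 2 of 480 in brightness, quantile normalization makes the brightest values alike on every array, so a change and the normalization cannot be told apart. Each slide held 1 sample, so slide and sample effects cannot be separated either, and a change in R9C hearts stays open and untested, as does the share of blood for miR-486, since miR-451 differed by −0.52.

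On the Agilent arrays, label numbers and RNA codes disagree. If the number named the RNA, arrays of one number and different codes would deviate together, but the 4 separate pairs had a mean correlation of −0.497, while the 5 separate pairs of one code had 0.654 (0.452 to 0.834). Centring mirrors the values in groups of 2 RNAs, so each such group counts once in each mean. WT (−0.706 and 0.706) and the internal control (−0.784 and 0.784) thus enter both with opposite sign, and the means are not independent. The R9C pairs alone had −0.436 and −0.0612 for one number and different codes, and 0.834, 0.496 and 0.452 for one code. Centring also pulls pairs of different R9C RNAs below 0. No biological explanation was tested.

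One hypothesis was that neighbouring miRNA genes change together. Of 407 mouse miRNAs, 355 were matched to genes of the mouse assembly GRCm38.p6. Pairs were taken within clusters whose successive genes start at most 10 kb apart, so members of a pair can lie further apart. Members of one name family were not paired. The differences of the 488 pairs in R9C against WT lay 0.138 log2 units apart on average, against 0.23 in 10000 permutations (permutation p = 0.003). Without the biggest cluster 113 pairs were left, with 0.14 against 0.229 (permutation p = 0.0011). Shared transcription would give such values, but similar probe sequences within clusters were not excluded. Neighbours that both lack signal would also lie close together, for example miR-302b (0.022) and miR-367 (−0.007), and the lenient filter keeps dim miRNAs. The test cannot tell these apart.

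Of the 35 splits of the 7 Exiqon samples, 1, the real one, gave as many as 44 higher calls (highest other 12) and 1 as many as 20 lower calls (highest other 13). The real split thus stood apart for these counts, which argues against chance. A share of 1 in 35 is the smallest that the splits allow, so chance is not excluded. For the lists, 9 splits called at least the 4 of the real one (highest other 6), so chance cannot be excluded. The split with 12 and 13 calls set R9C replicates 1 to 3 against WT with R9C replicate 4.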
